A study of Mus musculus with 5 samples.

How the data were processed

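The series measured RNA in 5 samples of mononuclear phagocytes sorted from mouse colon, 2 labelled CX3CR1+ and 3 labelled CD103+. Per the labels' protocols, complementary DNA was made with a low-input SMARTer kit (version 3), libraries were made with Nextera XT, and reads of 75 bases from both ends were taken on a NextSeq 500. Neither kit marks the strand of a transcript, so reads from a gene and an overlapping antisense gene cannot be told apart. The mm10 build, TopHat 1.0 and edgeR are named per the submitters' processing notes, which do not say what each was used for. The counting program, its annotation and its treatment of reads that match several genes are not given in the sources used here.

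The deposited values are raw read counts per gene, whole numbers that sum to a different total in each column, with genes named by Entrez Gene number. The table held 24453 genes. A further 1 column, whose name matches no sample analysed here, was not used here. Columns were matched to samples by their titles, groups came from the cell marker label, and replicates were numbered in accession order, so the replicate numbers pair no samples across groups. The sample titles carry running numbers that alternate between the groups, and whether neighbouring numbers mark samples of the same mouse or sort is not given in the sources used here. The labels do not say whether samples came from separate mice, so p-values measure the spread between these samples, which may be technical. No 2 libraries agreed within sampling noise, as tested by a chi-square of the counts of each pair over genes with at least 20 counts.

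Symbols and coordinates came from a RefSeq gene table of GRCm38.p6, the assembly of which mm10 is another name. It named 24373 of the Entrez numbers, and the 80 without a symbol held 0.277% to 0.513% of the counts and stayed in the tests. No mitochondrially encoded gene was in the table, so that list could not be tested. Of genes with at least 100 counts in total, 159 had the same counts in every library as another gene, such as the Ccl21 copies, and the hemoglobin gene pairs differed by no more than 2 counts. Reads were therefore counted for several near-identical genes, and the values of such genes are uncertain.

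Library totals ranged from 783261 to 2576052 counts, a 3.29-fold range. Counts were scaled by TMM, whose factors were 0.817 and 1.42 for the CX3CR1+ libraries and 1.02, 1.03 and 0.818 for the CD103+ libraries. CPM values are scaled by these factors. Genes past filterByExpr (17151) were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of F. The biological coefficient of variation was 0.718. An exact permutation test of 2 against 3 libraries cannot go below a one-sided p of 0.1 for any single value, and none is given.

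Gene lists were tested with camera and fry (limma 3.58.1) on log2 CPM with a prior count of 2, over lists with at least 3 tested members. There were 43 lists with 731 of 754 entries matched, of which 40 were tested as findings, 2 (sort genes and lineage exclusion genes) served as identity checks and 1 had no gene in the table. Genes named in the text followed a rule set before the data were examined. It took the genes of the sort and lineage gates, up to 12 genes in each direction past the test with a mean of at least 20 CPM and no overlap between groups, up to 4 members of each list with the smallest adjusted p, and 22 genes of cytokines, receptors and transcription factors. As no gene passed the edgeR test the second part named 0 genes, and since adjusted p values were tied the third was ordered by the unadjusted p. Not every gene that the rule took is given in the text. Actb, Eef1a1, Zfp488, Col3a1 and Sparc were chosen after their values were seen.

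A panel of 1542 protein-coding olfactory, vomeronasal and taste receptor and keratin-associated protein genes was summed per library as a measure of counts that do not come from expressed RNA of these cells. It was set up after the data were seen. Intervals of shares of counts are 95% exact binomial intervals (SciPy 1.17.1).

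The gene and list tests were run on simulated counts for these 17151 genes, with the means and library sizes of the 2 and 3 libraries. The changed genes and the list members were drawn from genes with a mean of at least 20 CPM, so recovery at lower levels was not measured. The 200 changed genes were split evenly between 4-fold and 16-fold. At the dispersions estimated from the data the test recovered 0% of the genes changed 4-fold and 21.3% of those changed 16-fold, with a mean of 1.67 false calls over 3 runs. At a dispersion of 0.1 it recovered 77.7% and 100% with 7.67 false calls. With all members of 5 lists changed 4-fold, camera recovered 5 of 5 and called 0 of 35 unchanged lists in either setting. The simulated genes varied independently, unlike genes of real lists.

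The alternatives tried were 3 other scalings, no filter, a filter of 10 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, robust empirical Bayes, a test against a fold change of 2, each library left out in turn, removal of hemoglobin genes, and thinning of all libraries to the smallest total. Gene lists were also tested with an estimated correlation, with fry, without each library, with RLE scaling and with the stricter filter. An alternative added after seeing the data kept 4 libraries, without CX3CR1+ replicate 2. It kept the 5866 genes whose expected background was under 20% of their mean count, of which 4289 passed the filter. The expected background was the count in CX3CR1+ replicate 2, scaled by the silent panel counts, so all counts of that library were taken as background. These are therefore genes with few counts in CX3CR1+ replicate 2.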

Results

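Mononuclear phagocytes, the macrophages and dendritic cells that take up material and present antigen, were obtained by cell sorting from the connective tissue under the colon epithelium of mice in which one Cx3cr1 allele carries the gene for green fluorescent protein. RNA was sequenced from 5 libraries in 2 groups, 2 labelled CX3CR1+ and 3 labelled CD103+, of which the latter are called dendritic cells in the labels. Both gates took live cells negative for lineage markers and positive for CD45, MHC class II, CD11b and CD11c, and then split them by CX3CR1, the receptor for fractalkine, or by CD103, the integrin encoded by Itgae. Whether the CX3CR1+ gate excluded CD103+ cells is not given in the sources used here. The library totals were 2576052 and 783261 counts for CX3CR1+ replicates 1 and 2, and 1667511, 975358 and 2118201 counts for CD103+ replicates 1, 2 and 3. The comparison of the 2 groups asks how the transcriptomes of the 2 sorted populations differ.

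CX3CR1+ replicate 2 had low counts of genes that were abundant in the other 4 libraries. Cd74, the invariant chain of MHC class II, had 460 counts in CX3CR1+ replicate 2 and 28025 in CX3CR1+ replicate 1, against 9012, 2475 and 6215 in CD103+ replicates 1 to 3. Actb, the cytoskeletal beta-actin gene, had 605 counts in that library and 11484, 7226, 4653 and 8612 in the other 4. A panel of 1542 genes of smell, taste and hair proteins, which colonic phagocytes are not known to use, took 28307 counts or 3.61% of that library (95% exact interval 3.57 to 3.66). Of these, 10725 counts (1.37%, 1.34 to 1.40) lay outside the 3 most abundant panel genes. The same panel took 28063 counts in CX3CR1+ replicate 1 and 29420, 18701 and 29241 counts in the libraries labelled CD103+, or between 1.09% (1.08 to 1.10) and 1.92% (1.89 to 1.94) of their totals. Outside those 3 genes it took 11141, 10505, 7189 and 11442 counts, or between 0.432% (0.425 to 0.441) and 0.737% (0.720 to 0.754). These intervals cover counting error only, since reads copied by PCR are not independent molecules.

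**Figure D1:**
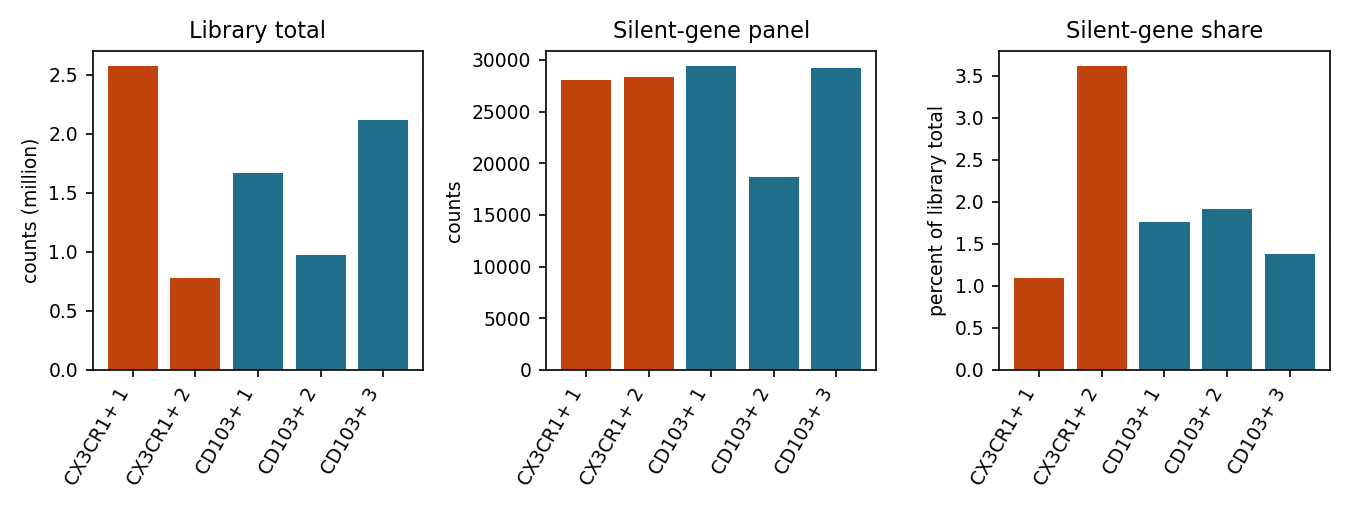
Bars give the total count per library, the counts in the panel of 1542 silent genes, and that panel's percent of the total, for the 2 libraries labelled CX3CR1+ (orange) and the 3 labelled CD103+ (blue), 1 bar per library. The totals ranged from 783261 to 2576052 counts while the panel stayed between 18701 and 29420 counts, so its share was highest, at 3.61%, in CX3CR1+ replicate 2.

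Of the 2 genes that name the gates, Cx3cr1 was low in every library and Itgae overlapped between the groups, so the group names are used below only as labels. Cx3cr1 (Entrez gene 13051, chromosome 9, 120048683 to 120068296 in GRCm38.p6) had 14 and 36 counts in the libraries labelled CX3CR1+ and 9, 3 and 11 in those labelled CD103+, too few to enter the test. Relative to the total count, without TMM, these were 5.43 and 46.0 against 5.40, 3.08 and 5.19 CPM, so that replicate 1 did not stand apart from the libraries labelled CD103+. Itgae (gene 16407, chromosome 11, 73090505 to 73147449) stood at 169 and 27.0 CPM, TMM-scaled counts relative to library size, in the libraries labelled CX3CR1+ and at 188, 218 and 126 CPM in those labelled CD103+. Its log2 fold change, CX3CR1+ over CD103+, was -0.85 ± 0.98 (SE, n = 2 and 3; edgeR adjusted p = 0.99999). Itgax, which encodes CD11c, stood at 287 CPM in CX3CR1+ replicate 1, 18.6 CPM in replicate 2 and between 76.7 and 133 CPM in the libraries labelled CD103+. The lineage genes that the gate excludes summed to 42.3 and 32.6 CPM in the libraries labelled CX3CR1+ and to 48.5, 43.3 and 43.3 CPM in the libraries labelled CD103+.

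Between the libraries labelled CX3CR1+ and CD103+ no single gene passed the edgeR test, and DESeq2 called 31, all higher in CD103+. Camera placed 7 gene lists toward CD103+ with a preset correlation between genes and 0 with an estimated one. In these 7 lists, genes lower in both libraries labelled CX3CR1+ than in all those labelled CD103+ were counted. They were 7 of 12 stromal, 3 of 10 endothelial, 4 of 15 epithelial and 4 of 21 immediate early and stress genes. They were also 7 of 23 apoptotic cell uptake and scavenger, 2 of 15 chemokine and 1 of 18 respiratory chain genes. Over all tested genes the share was 8.24%, and chance gives 10% where libraries are exchangeable. CX3CR1+ replicate 2 was low in many abundant genes, and for these the count rests on replicate 1 alone, where chance gives 25%. Higher in both were 1 scavenger receptor and 1 respiratory chain gene. In the other 33 lists 0 to 4 genes were lower in both and 0 to 3 higher in both. Of 27 core dendritic cell genes 3 were higher in both and 3 lower in both, of 15 MHC class II genes 1 was higher and 0 lower, and of 22 pattern recognition receptors 3 were higher and 1 lower. Tagln, a smooth muscle actin-binding protein, stood at 13.5 and 12.1 CPM in the libraries labelled CX3CR1+ and 233, 99.7 and 555 CPM in the libraries labelled CD103+ (log2 fold change -4.52 ± 1.17 SE). Areg, which encodes the growth factor amphiregulin, stood at 32.7 and 15.8 CPM against 1.80, 3.02 and 1.17 CPM (3.61 ± 0.96 SE). Clec7a, the beta-glucan receptor dectin-1, stood at 688 and 72.6 CPM against 62.3, 68.5 and 58.5 CPM (2.59 ± 0.99 SE). Spib, a transcription factor of plasmacytoid dendritic cells, stood at 93.3 and 12.1 CPM against 9.59, 5.04 and 10.5 CPM (2.63 ± 0.97 SE). In CX3CR1+ replicate 2 Areg had 17 counts and Spib 13, under the 95th percentile of the silent panel in that library, 29 counts.

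The edgeR quasi-likelihood test called 0 of 17151 genes, with 0 higher in either group and a smallest adjusted p of 0.99999. At an unadjusted p under 0.05 there were 770 genes, 365 higher in CX3CR1+ and 405 higher in CD103+, where 857.55 are expected by chance. The values of the 2 groups did not overlap for 1443 genes with CX3CR1+ above (8.41%) and 1413 with CX3CR1+ below (8.24%), and chance gives 10% in each direction. DESeq2 called 31 genes, 0 higher in CX3CR1+ and 31 higher in CD103+, among them Tagln, Acta2 and Fabp2, with 27 distinct sets of counts since Ccl21 copies share theirs, and limma-voom called 0 (574 at an unadjusted p under 0.05). Without CX3CR1+ replicate 1, only CX3CR1+ replicate 2 was left in that group. Broadly expressed genes were then far lower in CX3CR1+, such as Actb (log2 fold change -3.10) and Eef1a1 (-3.47). Zfp488, at 27284 to 45583 counts in the 5 libraries, stood slightly higher (0.53). These values are not read as traits of CD103+ cells, since CX3CR1+ replicate 2 was low in genes abundant in the other libraries.

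**Figure D2:**
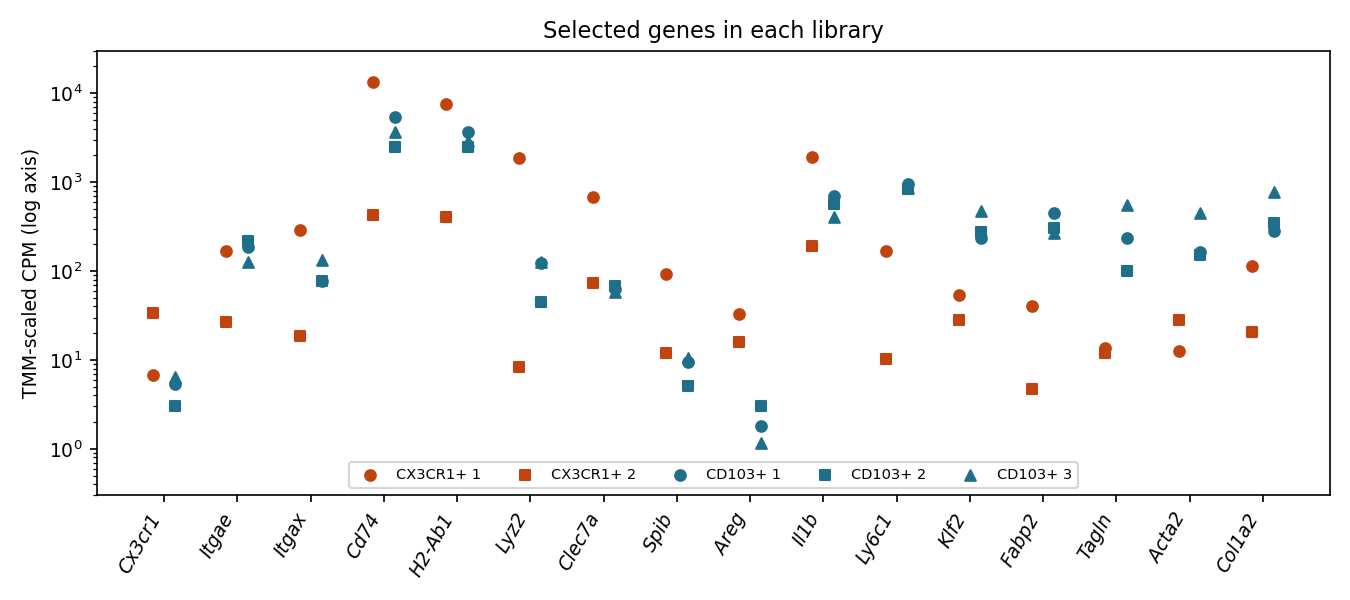
Each point is the TMM-scaled CPM of 1 gene in 1 library on a log axis, with the 2 libraries labelled CX3CR1+ in orange and the 3 labelled CD103+ in blue, and the shape giving the replicate number. Cd74 ranged from 428 CPM in CX3CR1+ replicate 2 to 13472 CPM in CX3CR1+ replicate 1, with the 3 libraries labelled CD103+ between them, while Tagln was at 13.5 CPM or less in both libraries labelled CX3CR1+ and at 99.7 CPM or more in the libraries labelled CD103+.

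Of 40 gene lists fixed before the data were examined, 7 lay toward CD103+ and 0 toward CX3CR1+ in the camera test with a preset correlation between genes of 0.01. With an estimated correlation 0 of the 40 passed (adjusted p = 0.803 for each of these 7), and with fry 0 passed (smallest adjusted p = 0.473). In 2 of the 7 the call held without CX3CR1+ replicate 2, and no gene of the 7 lists passed the edgeR test over all genes, while DESeq2 called Tagln and Acta2 of the stromal list and Fabp2 of the epithelial list. Over the lists, 3 genes passed when adjusted over the list alone, 2 in the stromal list and 1, Areg, in the list of natural killer and innate lymphoid cells.

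The stromal list, markers of fibroblasts and smooth muscle, had 12 tested members, 10 of them with a negative fold change and 7 lower in both libraries labelled CX3CR1+ than in every CD103+ library. Its median log2 fold change was -1.81 and its camera adjusted p was 3.6e-08. Acta2, smooth muscle actin, stood at 12.5 and 27.9 CPM in the libraries labelled CX3CR1+ and 165, 150 and 450 CPM in the libraries labelled CD103+. The collagen gene Col1a2 stood at 113 and 20.5 CPM against 282, 344 and 768 CPM. In the endothelial list 10 of 10 members had a negative fold change (median -1.29, adjusted p = 2.6e-04). Its member Plvap, a protein of fenestrated vessels, stood at 364 and 67.9 CPM against 644, 462 and 812 CPM. In the epithelial list 10 of 15 members were negative (median -0.71, adjusted p = 0.0252), among them Fabp2, a fatty acid binding protein of enterocytes, at 39.9 and 4.65 CPM against 454, 305 and 271 CPM. Without CX3CR1+ replicate 2 the median log2 fold change was -1.61 for the stromal, -0.65 for the endothelial and -1.16 for the epithelial list. Members with a positive fold change were then 2 of 12 stromal, 3 of 10 endothelial and 5 of 15 epithelial genes. The epithelial median was -1.67 without CX3CR1+ replicate 1 and -0.55 without CD103+ replicate 1 (camera adjusted p = 0.108). It was -0.86 without CD103+ replicate 2 (0.295) and -0.31 with the stricter filter (0.126).

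The list of immediate early and dissociation stress genes, which respond within minutes to handling of tissue, had 19 of 21 members with a negative fold change (median -0.97, camera adjusted p = 3.6e-08). Klf2, a transcription factor, stood at 53.4 and 27.9 CPM in the libraries labelled CX3CR1+ and 238, 274 and 469 CPM in the libraries labelled CD103+, and Egr1 at 359 and 34.4 CPM against 583, 736 and 627 CPM. Without CX3CR1+ replicate 2 this list's median was -0.10 and its adjusted p 0.730. The respiratory chain list, with 15 of 18 members negative (median -0.38, adjusted p = 0.0071), had a median of 0.52 without that library (adjusted p = 0.0857). The list of apoptotic cell uptake and scavenger receptors had 14 of 23 members negative (median -0.33, adjusted p = 0.0226) and an adjusted p of 0.0213 without that library. Its median was -0.61 without CX3CR1+ replicate 1, -0.16 without CD103+ replicate 1 (camera adjusted p = 0.114) and -0.57 without CD103+ replicate 3 (0.0536). Its members Axl, a receptor for dying cells, and Mfge8, a bridging protein that binds them, stood at 9.13 and 4.65 CPM and at 8.65 and 21.4 CPM in the libraries labelled CX3CR1+ respectively, and in the libraries labelled CD103+ Axl stood at 43.8, 48.4 and 48.5 CPM and Mfge8 at 92.3, 43.3 and 225 CPM. The chemokine list had 12 of 15 members negative (median -1.06, camera adjusted p = 0.0154), and without CX3CR1+ replicate 2 its median was -0.87. Cxcl1, a neutrophil attractant, stood at 66.3 and 3.72 CPM against 86.3, 129 and 676 CPM, with its highest value in CD103+ replicate 3. Without CD103+ replicate 3 the median of the list was -0.08 (camera adjusted p = 0.496).

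The remaining 33 lists did not pass (smallest adjusted p = 0.0729). Without CX3CR1+ replicate 1, 14 of them passed, 13 toward CD103+, and without CX3CR1+ replicate 2, 12 passed, all 12 toward CX3CR1+, with a preset correlation. Among macrophage genes, 17 of 33 core members and 9 of 25 intestinal macrophage members had a positive fold change (adjusted p = 0.542 and 0.227). Lyz2, a lysozyme of myeloid cells, had 3896 counts in CX3CR1+ replicate 1, 9 in replicate 2 and 203, 45 and 215 in the libraries labelled CD103+. Fcgr1, an antibody receptor of macrophages, had 2 and 11 counts in the libraries labelled CX3CR1+ and 36, 3 and 5 in the libraries labelled CD103+, and Mertk, a receptor for dying cells, had 4 and 33 against 42, 12 and 9. Among dendritic cell genes, 19 of 27 core members, 9 of 17 type 1 members, 12 of 16 type 2 members and 8 of 10 plasmacytoid members had a positive fold change (adjusted p = 0.226, 0.9997, 0.540 and 0.0767). The core list passed toward CX3CR1+ without CX3CR1+ replicate 2 (0.0028), without CD103+ replicate 3 (0.0322) and with 4 libraries and low-background genes (0.0056, median 1.20), and with an estimated correlation these stood at 0.480, 0.911 and 0.697. Xcr1, a chemokine receptor of type 1 dendritic cells, stood at 73.6 and 109 CPM in the libraries labelled CX3CR1+ and at 89.3, 57.4 and 103 CPM in the libraries labelled CD103+. Its highest value was in CX3CR1+ replicate 2, where the silent panel took its largest share. These Xcr1 values are therefore not read as levels in cells.

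MHC class II genes depended on which CX3CR1+ library was read. Of the 15 members of that list 11 had a positive fold change (median 0.66, adjusted p = 0.998, with the camera test pointing the other way). H2-Ab1, a class II beta chain, stood at 7630 and 407 CPM in the libraries labelled CX3CR1+ and 3650, 2499 and 2909 CPM in the libraries labelled CD103+, with a log2 fold change of 0.41 ± 0.999 (SE). The median, the mean and the camera direction differed in sign in 11 of the 40 lists, all among those that did not pass. Among the cytokine genes named here, Il1b differed between the libraries labelled CX3CR1+, and Tnf and Il10 mostly among those labelled CD103+. Il6 was lower in both libraries labelled CX3CR1+ than in every library labelled CD103+, as were 8.24% of all tested genes, and did not pass the edgeR test. Il1b stood at 1902 and 190 CPM in the libraries labelled CX3CR1+ and 698, 565 and 410 CPM in the libraries labelled CD103+, and Il6 at 19.7 and 21.4 CPM against 86.9, 53.4 and 243 CPM (log2 fold change -2.63 ± 1.04 SE). Tnf stood at 2.40 and 1.86 CPM against 42.6, 1.01 and 143 CPM. Il10, the regulatory cytokine, had 2 counts in each of 4 libraries and 31 in CD103+ replicate 3. Aldh1a1, a retinoic acid synthesis enzyme, stood at 4.81 and 1.86 CPM against 5.99, 73.5 and 91.2 CPM, and Aldh1a2, another such enzyme, at 15.9 and 34.4 CPM against 21.0, 69.5 and 11.7 CPM. In the list of retinoic acid and TGF-beta activation 15 of 18 members had a negative fold change (median -0.71, adjusted p = 0.113).

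Among lists of other cell types, those of T cells (adjusted p = 0.540), B and plasma cells (0.540), natural killer and innate lymphoid cells (0.458), neutrophils (0.998), eosinophils (0.566), mast cells and basophils (0.226) and enteric glia and neurons (0.227) did not pass. Summed over the erythroid list, whose hemoglobin pairs count the same reads for both genes, the level was 200565 CPM in CD103+ replicate 3. In the other 4 libraries the sum was 8565 to 66658 CPM. In the erythroid list 7 of 7 members had a negative fold change (median -1.11, camera adjusted p = 0.0840). As most of them are paired hemoglobin genes with near-identical counts, the list holds fewer separate measurements than members. It passed without CX3CR1+ replicate 1 (0.0020), CD103+ replicate 1 (0.0240) or CD103+ replicate 2 (0.0027), at 0.522, 0.890 and 0.913 with an estimated correlation, and without CD103+ replicate 3 its median was 0.43 (0.724). Monocyte genes (adjusted p = 0.113), pattern recognition receptors (0.327), lysosomal genes (0.350), MHC class I genes (0.0998), interferon response genes (0.698), cell cycle genes (0.302) and glycolytic genes (0.664) did not pass either. In the monocyte list 9 of 14 members had a positive fold change (median 0.27, mean -0.43). The list passed the camera test toward CD103+ without CD103+ replicate 1 (0.0329, and 0.890 with an estimated correlation), where its median was 0.045. Without CX3CR1+ replicate 1 its median was -1.73.

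**Figure D3:**
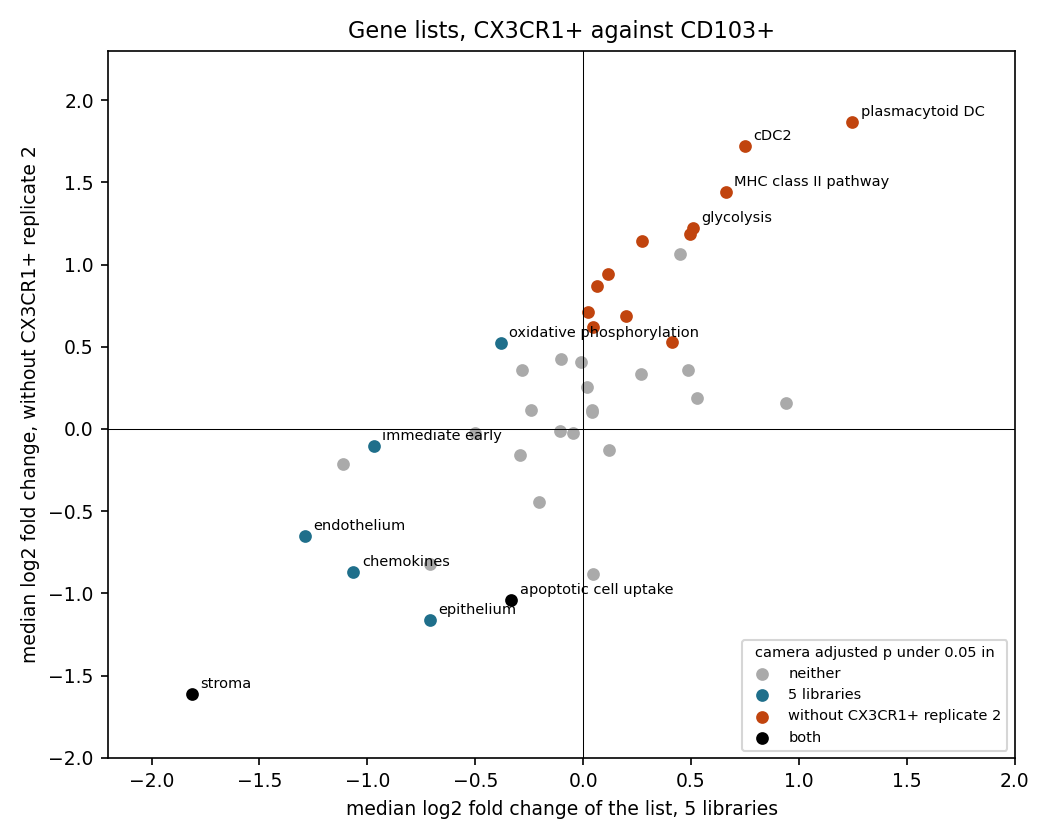
Each point is 1 of 40 gene lists, placed by the median log2 fold change of its members (CX3CR1+ over CD103+) with 5 libraries on the x axis and without CX3CR1+ replicate 2 on the y axis, and coloured by where its camera adjusted p was under 0.05. The stromal list lies low on both axes (-1.81 and -1.61), while the respiratory chain list moves from -0.38 to 0.52.

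Libraries of 1 group were not all nearer to each other than to the other group. Over the tested genes the Spearman correlation of log2 CPM was 0.617 ± 0.027 (SD, n = 3 pairs) within CD103+ and 0.397 between the libraries labelled CX3CR1+. CX3CR1+ replicate 1 correlated with the libraries labelled CD103+ at 0.632 ± 0.026 (SD, n = 3 pairs) and CX3CR1+ replicate 2 at 0.438 ± 0.012. The first principal component held 37.2% of the variance and placed CX3CR1+ replicate 2 at 140 and the other 4 libraries between -87.0 and 5.22.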

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

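The alternative with 4 libraries and low-background genes was chosen after seeing the data, and the others before the data were examined. The count of 0 genes held in edgeR with RLE, upper-quartile and no scaling, with either filter, with robust empirical Bayes, with the fold test, without hemoglobin genes, after thinning, in limma-voom and with the added low-background genes (225 to 1197 genes at an unadjusted p under 0.05). DESeq2 called 31 genes, 0 higher in CX3CR1+ and 31 higher in CD103+. Leaving out 1 library gave 0 to 139 genes, of which 0 to 1 were higher in CX3CR1+ and 0 to 138 higher in CD103+. The 139 came without CX3CR1+ replicate 1, where the one library left in that group was CX3CR1+ replicate 2 and was assumed to vary like the CD103+ libraries, and 6 of them were among the 31. Of these 6 genes 5 had identical counts, so that 2 distinct measurements were shared, and the 139 and 31 held 134 and 27. Genes called without CX3CR1+ replicate 1 included the broadly expressed Actb and Eef1a1, so they are not read as particular to CD103+ cells. Upper-quartile scaling moved the median log2 fold change of all genes by 0.15 and no scaling by 0.19.

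The 7 lists called by camera became 0 with an estimated correlation, 0 with fry in one direction and 0 with fry in either direction. Leaving out 1 library gave 6 to 19 lists, the 19 without CX3CR1+ replicate 1, and 14 without CX3CR1+ replicate 2. With 4 libraries and low-background genes 2 were called, stroma (0.0035) toward CD103+ and core dendritic cell genes (0.0056) toward CX3CR1+. RLE scaling gave 7 and the stricter filter 6. Over the left-out libraries the camera adjusted p ran from 4.15e-08 to 0.0024 for stroma, 1.4e-05 to 0.319 for endothelium, 1.0e-14 to 0.730 for immediate early genes, 0.0188 to 0.138 for scavenger receptors, 0.00098 to 0.742 for chemokines and 0.0322 to 0.295 for epithelium.

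Of 2832 values of 177 named genes under the alternatives, 103 changed sign. With the sign kept 8 passed the test, in DESeq2 or without CX3CR1+ replicate 1. Among the 103 with a changed sign, 4 passed it. These 4 were class II genes without CX3CR1+ replicate 1. Over the left-out libraries the log2 fold change ran from -2.93 to 1.36 for H2-Ab1, -2.74 to 1.44 for H2-Aa, -4.02 to 1.68 for H2-Eb1 and -3.21 to 1.83 for Cd74. Of 433 list values 362 stayed on their side of the threshold, 39 lost and 24 gained a call, and 8 turned direction without CX3CR1+ replicate 1 or 2. Those 8 lists had camera adjusted p values, over the left-out libraries, of 0.0150 to 0.985 for type 1 and 0.00071 to 0.847 for type 2 dendritic cells, 0.0118 to 0.971 for dendritic cell maturation, 2.6e-06 to 0.799 for lysosome, 0.0011 to 0.847 for MHC class II, 1.9e-08 to 0.221 for MHC class I, 0.00071 to 0.820 for glycolysis and 5.3e-10 to 0.0857 for the respiratory chain. For these genes and lists the cause was not tested. With a prior count of 0.5 the Pearson correlation moved from 0.689 to 0.654 within CD103+ and from 0.457 to 0.432 within CX3CR1+.

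No paired analysis was possible because the labels give the groups no shared replicate number. No block on neighbouring title numbers was fitted, since no label says that they pair samples. Spread limited what was called, since at the same library sizes 0% of simulated 4-fold changes were recovered at the estimated dispersions and 77.7% at a dispersion of 0.1. Thinned to the smallest total, 12566 genes passed the filter in place of 17151.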

Other observations

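The tests of explanations given here were chosen after the result was seen, except the thinning test and the second stromal list. Without CX3CR1+ replicate 2, 1 library labelled CX3CR1+ is left against 3 labelled CD103+, and its spread is taken from the CD103+ group. The edgeR test then called 0 of 18586 genes (1221 at an unadjusted p under 0.05, smallest adjusted p = 0.329). The genes named in this paragraph were chosen after their values were seen. Those with the smallest p included Lyz2 (log2 fold change 4.28 ± 0.54 SE) and Clec7a (3.47 ± 0.52 SE), both of myeloid cells, and the class II genes H2-Eb1 (1.68 ± 0.28 SE) and Cd74 (1.83 ± 0.32 SE), all higher in CX3CR1+ replicate 1. The broadly expressed Ubc (1.41) and Fth1 (1.63) were among them too. Positive members were 18 of 19 for MHC class I, 15 of 17 for glycolysis and 15 of 18 for the respiratory chain, against 2 of 12 for stroma. The higher values are therefore not read as particular to myeloid genes, and CX3CR1+ replicate 1 also had the lowest silent-panel share, 1.09%. Il22ra2, a decoy receptor for the cytokine IL-22 made by dendritic cells, had 533 counts in that library and 15, 16 and 38 in the CD103+ libraries. Ly6c1, a surface protein found on vessel endothelium, was at 170 CPM against 949, 842 and 861 CPM. Camera placed 12 lists toward CX3CR1+ replicate 1, led by plasmacytoid dendritic cells (adjusted p = 1.9e-04, median log2 fold change 1.87), type 2 dendritic cells and glycolysis (7.1e-04 each) and MHC class II (0.0012, median 1.44). With an estimated correlation 0 passed (smallest adjusted p = 0.480).

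Red cell and sex-linked genes also differed between libraries of 1 group. Hemoglobin genes took 16.2% of counts in CD103+ replicate 3 (95% exact interval 16.1 to 16.2). They took 3.30% (3.28 to 3.33) and 2.63% (2.60 to 2.66) in CD103+ replicates 1 and 2. The hemoglobin genes came in pairs with near-identical counts, so the same reads were counted for both genes of a pair. These values are therefore too high as shares of reads, and the intervals do not cover this. The Y-linked gene Ddx3y had 240 and 17 counts in the CX3CR1+ libraries and 64, 7 and 61 in the CD103+ libraries, and Xist, which is transcribed from the inactive X, had 265, 80, 238, 121 and 343 counts in the same order. Plp1, a gene of enteric glia, had 232 counts in CX3CR1+ replicate 1 and 7, 19, 5 and 22 in the others.

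CX3CR1+ replicate 2 stood apart from the other 4 libraries. Lower depth alone is argued against, since with all libraries thinned to its total the other 4 still correlated at 0.609 with each other and 0.420 with it, a gap of 9.32 SD of the 6 pairs. A property of CX3CR1+ cells stays open, since the silent-gene share of CX3CR1+ replicate 1, 1.09% (95% exact interval 1.08 to 1.10), was below the lowest CD103+ library at 1.38% (1.36 to 1.40), but that is 1 library whose label is itself in doubt. Few reads from cells over a background of similar size in every library is a candidate explanation, as the silent panel held 0.988 times the median count of the other 4 libraries (0.991 without its 3 most abundant genes) while the total held 0.414 times theirs. If all counts of CX3CR1+ replicate 2 were background, the silent panel would allow background of up to 30.1% in CX3CR1+ replicate 1. In CD103+ replicates 1 to 3 it would allow up to 48.8%, 53.1% and 38.2%. The CPM values and fold changes given here were not corrected for such a background. What made the background (genomic DNA, other samples or the alignment) was not tested.

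Cx3cr1 was low in every library (14 and 36 counts in the libraries labelled CX3CR1+ and 9, 3 and 11 in the others, or 5.43 and 46.0 against 5.40, 3.08 and 5.19 CPM of the total), and Itgae overlapped between the groups. Cx3cr1 reads at the level of the background could neither be shown nor ruled out, since the Cx3cr1 count lay between the 60.6th and 89.2nd percentile of the silent panel in 4 libraries and at the 95.9th in CX3CR1+ replicate 2. A wrong group label on CX3CR1+ replicate 1 cannot be told apart from CD103+ cells inside the CX3CR1+ gate, since Itgae at 169 CPM lay within the CD103+ range of 126 to 218 CPM and the labels name no gate against CD103. The replacement of 1 Cx3cr1 allele, which is given for the mice of both groups, was not tested as a reason for low Cx3cr1 counts.

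Of 12 tested stromal genes 10 had a negative fold change, and 7 were lower in both libraries labelled CX3CR1+ than in every CD103+ library. None of them passed the edgeR test over all genes. With 5 libraries the camera adjusted p of the list was 3.6e-08 with the preset correlation and 0.803 with an estimated one, and fry gave 0.473. Without CX3CR1+ replicate 2 the median log2 fold change was -1.61, against -1.81 with it, so that library alone does not make the fold. As 1 library labelled CX3CR1+ is then left, whether few reads from cells in CX3CR1+ replicate 2 explain the group difference cannot be decided. RNA of stromal cells in the CD103+ libraries is a candidate explanation. Of a second list of 26 stromal genes, which shares no member with the first, 15 (57.7%) were higher in each CD103+ library than in CX3CR1+ replicate 1. The share was 27.0% over all tested genes. As the second list was read in the same libraries as the first, it cannot separate this explanation from other reasons for low stromal counts in CX3CR1+ replicate 1. The abundant collagen genes Col3a1 and Col1a2 were at 206 and 113 CPM in CX3CR1+ replicate 1 and at no less than 323 and 282 CPM in the CD103+ libraries, but Sparc was at 973 CPM in that library and 646 CPM in CD103+ replicate 2, and since the CD45 gate would remove such cells, free RNA and a difference between the 2 populations both stay open.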
